A study of Mus musculus with 5 samples.

How the data were processed

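Gene expression was measured in the esophagus of IL-13 transgenic mice in 5 arrays, 3 on a doxycycline diet (Dox) and 2 on a regular diet (NoDox), grouped by their titles. Per the labels' protocols, total RNA was extracted with Trizol, labelled with biotin by random priming and hybridised to Affymetrix Mouse Genome 430 2.0 arrays. Per the submitters' processing notes, signals were made with Microarray Suite (MAS 5.0) at default settings and normalized pair-wise in GeneSpring 7.3.1 against unstimulated controls. The deposited values are in the unit ratio, a linear ratio made by the authors. Checked on the values, each is a signal divided by the mean of the 2 NoDox arrays, since the NoDox values of a probe set sum to 2, within 0.0001, in 45099 of 45101 probe sets. The values thus show a common NoDox mean as the reference, not a separate control for each array, which differs from the pair-wise normalization the notes state. The lowest value is 0.01, which 6 values hold. The deposited ratios carry no signal level and no detection call. The number of arrays limits the precision.

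The signal level was recovered from the ratios, because a ratio of signals stored as whole multiples of a fixed step has few solutions. For each of 45098 probe sets, whole step numbers up to 50000 that give its 5 ratios within a relative tolerance of 3e-07 were searched, with a limit of 0.01 expected chance solutions. A level was found for 40710 (90.3%), and for 130 of 4000 probe sets with ratios shuffled between probe sets (3.25%). Probe sets without a solution were given a lower bound as their level. On 45000 simulated probe sets, 99.96% of the recovered levels were right. An earlier form of the rule, up to 30000 steps with no limit on chance solutions, was replaced after a first fit had been seen.

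Log2 ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of adjusted p under 0.05. No offset was added and no filter on level was applied. The plan, set before the data were examined, took the mean log2 value of a probe set both for the intensity trend and for choosing the probe set of a gene. For ratios to the NoDox mean that value follows the fold change itself. The recovered level was therefore used in its place, a departure from the plan that was decided before any test was run. The mean log2 ratio was also tried for the trend alone and for the probe set alone. Read to the letter, the plan gives 0 genes higher and 0 lower. Of the probe sets 34945 have 1 gene symbol, 932 several and 9160 none, and 64 are controls. The probe set of highest level stood for each of 18193 genes. The fit has 3 residual degrees of freedom and 6.01 prior ones. An exact permutation test of 3 against 2 arrays cannot give a p below 0.1, so single values per array were not tested.

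Gene lists of the IL-13 response, of cell types, of neighbouring tissues and of sample handling, 34 in all, were written from general knowledge before the data were examined. They were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of them 19 were higher and 7 lower with the preset correlation, and 1 and 0 with the estimated one. A current gene symbol was never read as another gene's older name, a rule corrected after values had been seen. The named genes are 101 in number. They are the genes fixed in advance, the 10 largest rises and falls past the threshold with Dox arrays on one side of both NoDox arrays, the 3 members of smallest p in each list past the threshold, and a few sex-linked genes. Other list members that the text names were chosen after their values were seen.

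The fit was tested on simulated data with the same numbers of genes and arrays, each gene drawn independently with a spread taken from the fit itself. With no change it called 0 genes. Of 200 genes changed 2-fold, 4-fold and 8-fold it called 46, 113 and 142, with 4 false calls each time. Camera called 0 lists with no change and 3, the raised one among them, with 1 list raised. Some lists share genes, but the cause of the further calls was not tested. The simulated genes were not correlated, so this does not show how camera behaves where genes of a list vary together. Alternatives were tried for the scaling, offset, level filter, choice of probe set, variance model, array weights, replicate numbers, threshold and single arrays. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.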

Results

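RNA of the esophagus was hybridised to Affymetrix Mouse Genome 430 2.0 arrays in a transgenic mouse line that makes the type 2 cytokine IL-13 on demand. In these FVB/N mice, aged 3 to 4 months, the CC10 promoter, which is active in airway club cells, drives a transactivator that switches on an IL-13 transgene when doxycycline is given. The Dox group (n = 3 arrays) came from mice on a doxycycline diet and the NoDox group (n = 2 arrays) from mice on a regular diet. Each of the 45101 probe sets has 1 value per array, a ratio to the mean of the 2 NoDox arrays. The number of arrays limits the precision. The labels do not say that each array is a separate animal, so p-values measure the spread between these arrays only. Doxycycline-fed mice without the transgene were not analysed here, so the diet and the induced IL-13 are not separated in any comparison.

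The comparison asked how gene expression in the esophagus differs between the doxycycline diet and the regular diet. In Dox, known target genes of IL-13 rose, with the lipoxygenase Alox15 77.1-fold higher and the chitinase-like gene Chil3 47.5-fold higher. Among 29 macrophage genes 12 rose, and among 20 of antigen presentation 6, list shifts that did not hold with an estimated correlation (adjusted p = 0.148 and 0.213). The keratins Krt6a, Krt6b and Krt16 rose, and the muscle genes Myl2, Myh7, Tnnc1 and Myh4 fell, with the myosin light chain Myl2 62.1-fold lower. Of 18193 genes tested with limma and Benjamini-Hochberg adjustment, 249 were higher and 213 lower in Dox at adjusted p under 0.05, and 191 and 96 of them changed at least 2-fold. All 462 changed genes had the 3 Dox arrays on one side of both NoDox arrays, which the test itself favours. Such a separation held for 6478 of the genes tested (35.6%), where chance gives 20%. All genes share the same arrays, and the median ratios of Dox replicates 1, 2 and 3 were 0.955, 0.952 and 0.926. The excess over 20% was therefore not tested. The split was 327 higher to 125 lower with quantile normalization, and 294 to 146 with each array centred on its median ratio. The fit uses a signal level recovered from the deposited ratios, for a trend of the spread and for the choice of each gene's probe set. With the mean log2 ratio in place of that level in both, limma called 0 genes higher and 0 lower (2180 genes at unadjusted p under 0.05). With the mean log2 ratio for the trend alone it called 0 and 0 (2363 at unadjusted p under 0.05), and for the probe set alone 259 and 119. With no trend it called 6 higher and 0 lower (2421 at unadjusted p under 0.05, against 3153 as reported). Single arrays also moved the counts, to 377 and 486 without Dox replicate 2, 117 and 47 without Dox replicate 3, 59 and 8 without NoDox replicate 1, and 64 and 11 without NoDox replicate 2.

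Values below are log2 fold changes ± SE from 3 Dox and 2 NoDox arrays. Of 69 named genes past the threshold 28 kept their call in all 5 fits with 1 array left out, and the loss of a call is given below as the number of these fits with the highest adjusted p in brackets. The largest rise among genes past the threshold was that of Gsdmc2, of the gasdermin C family, at 8.07 ± 0.62 (adjusted p = 0.000292, limma with Benjamini-Hochberg adjustment), with ratios of 258, 127 and 259 in the Dox arrays. Alox15 rose by 6.27 ± 0.13, Chil3 by 5.57 ± 0.13 and its paralog Chil4 by 5.54 ± 0.15. Mrgprg, a receptor gene of the Mas-related family, rose by 5.72 ± 0.49, the plasma protein gene Itih4 by 5.39 ± 0.61 and the macrophage elastase Mmp12 by 5.39 ± 0.56. The eosinophil-associated ribonuclease genes Ear3 and Rnase2b rose by 5.14 ± 0.22 and 4.91 ± 0.22. Ripply2 rose by 5.00 ± 0.67, with ratios from 10.5 to 79.0 in the Dox arrays and a signal level that was not recovered. Ripply2 lost its call in 2 fits (0.131). With a larger offset added to the signal Gsdmc2 shrank to 3.35, Mrgprg to 2.59, Itih4 to 1.70 and Mmp12 to 2.80. The first rank of Gsdmc2 was therefore lost with the larger offset, since over all alternatives Alox15 stayed at or above 4.89. Chil3 and Chil4 stayed at or above 4.87 and 4.75. Their levels were not recovered, so no offset was added to them and they could not shrink in this way. Chil3 and Chil4, and the members of the Gsdmc and of the Ear and Rnase2 families, share sequence, so which member changed is uncertain. The largest falls were those of Myl2 (-5.96 ± 0.35), the sulfotransferase Sult1d1 (-4.10 ± 0.43), the transporter gene Slc22a30 (-4.07 ± 0.81) and the slow myosin heavy chain Myh7 (-4.04 ± 0.25). The fast myosin heavy chain Myh4 fell by 3.06 and the slow troponin Tnnc1 by 2.96 on the log2 scale. Rps6ka6 (-2.71 ± 0.41), Lyg1 (-2.58 ± 0.40), the galanin receptor Galr2 (-2.30 ± 0.35) and Nnat (-2.27 ± 0.41) completed the 10 largest falls. Slc22a30 was dim, its log2 fold change shrank to -0.60 with the larger offset, and its call held in 1 of the 5 fits with 1 array left out, that without Dox replicate 2 (adjusted p up to 0.292 in the others, and 0.0208 to 0.857 over all alternatives). Rps6ka6, Lyg1, Galr2 and Nnat each lost their call in 3 of these 5 fits (adjusted p up to 0.167, 0.163, 0.170 and 0.249) and Sult1d1 in 2 (up to 0.0825). Sult1d1 shrank to -1.93 with the larger offset, and Rps6ka6 to -0.75 with another probe set.

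**Figure D1:**
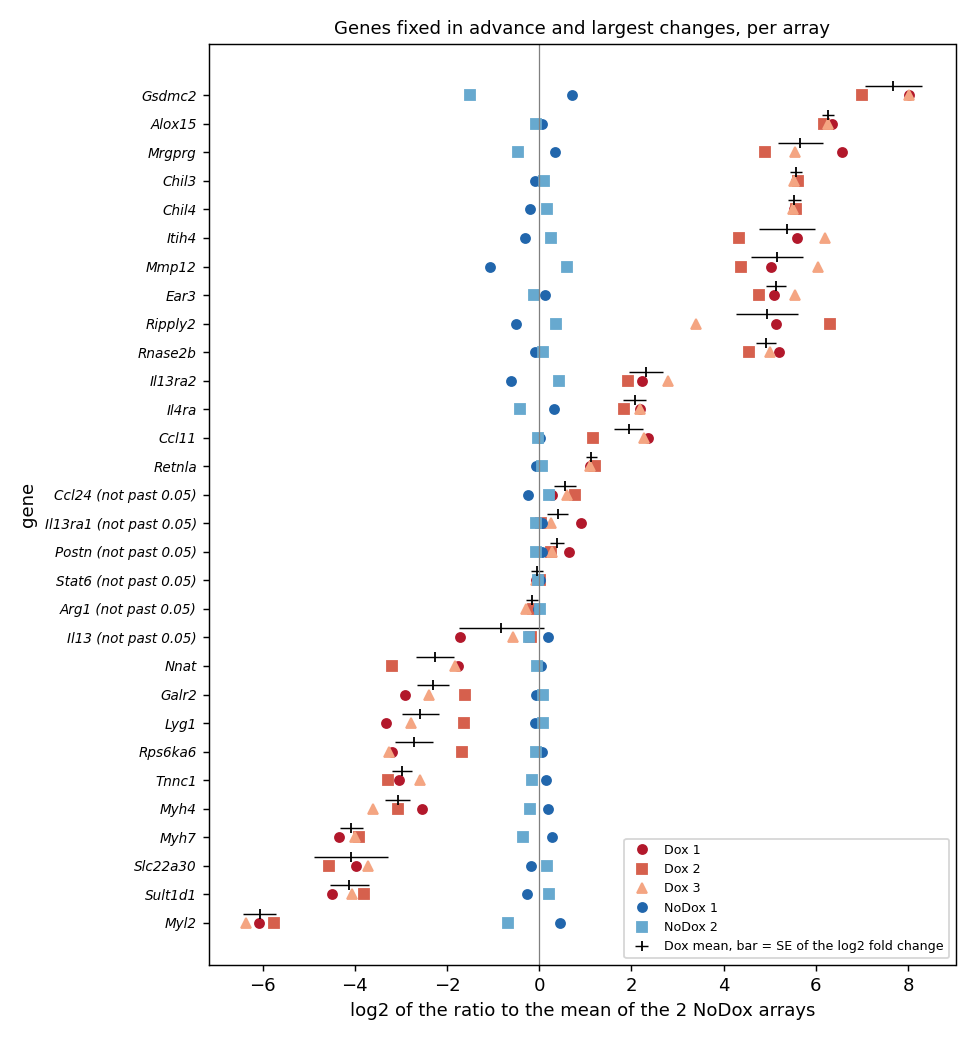
Log2 ratio to the mean of the 2 NoDox arrays (horizontal axis) of the genes fixed in advance and the 10 largest rises and falls (vertical axis), 1 point per array; the black tick is the Dox mean and its bar the SE of the log2 fold change. The 3 Dox arrays lie at ratios of 72.0 to 82.0 for Alox15 and of 0.0122 to 0.0186 for Myl2.

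The IL-13 pathway was read first from genes fixed before the data were examined. Il4ra, the receptor chain shared by IL-4 and IL-13, rose by 2.11 ± 0.25 (adjusted p = 0.00307, limma with Benjamini-Hochberg adjustment), and Il13ra2, the decoy receptor of IL-13, by 2.40 ± 0.37 (adjusted p = 0.0126). The eosinophil chemokine Ccl11 rose by 1.94 ± 0.31 and the secreted type 2 marker Retnla by 1.13 ± 0.13. Ccl11 lost its call in 3 of the 5 fits with 1 array left out (adjusted p up to 0.166), and Il13ra2 (0.132) and Retnla (0.0827) in 2. Il13ra2 shrank to 1.37 with the larger offset. The Il13 transcript itself was dim and not past the threshold, at -0.81 ± 0.92 (adjusted p = 0.711). Il13ra1 (0.40), Ccl24 (0.57), Postn (0.39) and Arg1 (-0.16) were not past it either, nor was Stat6 (-0.05), whose sign changes with quantile normalization and with median centring. Of 34 genes in the IL-13 response list, 14 rose and 0 fell over all genes, and 18 rose and 1 fell adjusted over the list alone. Beside Alox15, Chil3 and Chil4 they included the monocyte chemokine Ccl8 (3.47 ± 0.16), the lectin Itln1 (4.67 ± 0.56) and the lipoxygenase Alox12e (2.70 ± 0.18). This list, raised in limma's camera test (camera adjusted p = 6.91e-23, and adjusted p = 0.0456 with an estimated correlation), was the single one of 34 to pass the threshold in both. In the list of the IL-4 and IL-13 receptor pathway 3 of 16 genes rose, Il4ra, Il13ra2 and the feedback inhibitor Socs3 (0.89 ± 0.13, a call lost in 3 fits, adjusted p up to 0.153), and 5 rose adjusted over the list alone (camera adjusted p = 5.14e-05, and adjusted p = 0.164 with an estimated correlation).

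Lists of macrophages, antigen presentation, chemokines and the interferon response shifted upward in Dox at the preset correlation, and none of these shifts held with an estimated one. With fry, macrophages (fry adjusted p = 0.0251), chemokines (0.0377) and the interferon response (0.00569) passed the threshold, and antigen presentation did not (0.0655). Of 29 macrophage genes 12 rose, among them the lysosomal Cd68 (1.54 ± 0.15), Mmp12 and the signalling adaptor Tyrobp (1.42 ± 0.18), and 22 rose adjusted over the list alone (camera adjusted p = 6.91e-23, and adjusted p = 0.148 with an estimated correlation). Of 20 genes of dendritic cells and MHC class II 6 rose, led by H2-Ab1 (1.69 ± 0.15), the Langerhans cell lectin Cd207 (2.53 ± 0.22) and the invariant chain Cd74 (1.58 ± 0.20). Adjusted over the list alone 12 rose (camera adjusted p = 3.55e-13, and adjusted p = 0.213 with an estimated correlation). Of 34 chemokine genes 6 rose, led by Ccl8, by Cxcl15, a chemokine of lung epithelium (3.41 ± 0.37), and by Ccl6 (1.30 ± 0.18). In this list 11 rose adjusted over the list alone (camera adjusted p = 4.63e-11, and adjusted p = 0.165 with an estimated correlation). The surfactant gene Sftpc, a marker of lung, rose in the same arrays (2.18 ± 0.24). Of 35 interferon response genes 5 rose, led by the antiviral Oas1a (1.41 ± 0.16) and the immunoproteasome subunits Psmb8 (1.23 ± 0.16) and Psmb9 (1.23 ± 0.17). A total of 13 rose and 1 fell adjusted over the list alone (camera adjusted p = 7.32e-11, and adjusted p = 0.0735 with an estimated correlation). Tyrobp lost its call in 1 fit, without NoDox replicate 1 (0.106), Cxcl15 in 1, without NoDox replicate 2 (0.0509), and Cd74 (0.0941), Ccl6 (0.143), Sftpc (0.0618), Oas1a (0.0664), Psmb8 (0.104) and Psmb9 (0.143) in 2.

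Lists of granulocytes, lymphocytes and cytokines shifted upward at the preset correlation, each with at most 2 members past the threshold over all genes. Of 10 eosinophil genes Alox15, which epithelium and macrophages also make, and Ear3 rose, and 4 rose adjusted over the list alone (camera adjusted p = 6.09e-05, and adjusted p = 0.213 with an estimated correlation). Adgre4 (1.81), the granule protein genes Prg2 (-1.09) and Epx (-0.17) and the receptors Il5ra (0.09) and Ccr3 (0.07) were not past the threshold. Of 15 neutrophil genes the iron-binding Lcn2, which epithelium also makes, rose by 3.83 ± 0.45, while Mmp9 (1.22) and Il1r2 (-0.86) were not past the threshold. Adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.0243, and adjusted p = 0.213 with an estimated correlation). Among 30 cytokine and alarmin genes Tgfb1 rose (1.01 ± 0.19) and Il18 fell (-0.75 ± 0.16), and Hbegf was at 0.98. The calls of Tgfb1 (0.284) and Il18 (0.299) were lost in 4 of the 5 fits with 1 array left out, and those of Lcn2 (0.0655) and the IgA heavy chain Igha (0.281) in 2. In this list 6 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.0247, and adjusted p = 0.213 with an estimated correlation). Of 26 T and NK cell genes 0 passed limma's test over all genes and 1 rose adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.354 with an estimated correlation). Il7r (1.60), Nkg7 (1.34) and Thy1 (-0.55) had its smallest p-values. The shifts of the neutrophil, cytokine and T and NK cell lists ended with quantile normalization and with median centring. Over the alternatives their adjusted p reached 0.284, 0.865 and 0.377. Of 21 genes of B and plasma cells the secretory gene Derl3 (3.17 ± 0.31) and Igha (2.78 ± 0.54) rose, Iglv1 was at 3.59, and 5 rose adjusted over the list alone (camera adjusted p = 8.72e-07, and adjusted p = 0.351 with an estimated correlation). In this last list 19 genes had a log2 fold change above 0, and its median log2 ratio was 0.25, 0.60 and 3.22 in Dox arrays 1, 2 and 3.

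In the epithelium 3 keratins of activated keratinocytes and 4 small proline-rich genes rose while 4 of 54 squamous genes fell, and no list shift there held with an estimated correlation. Krt6b rose by 2.55 ± 0.14, Krt6a by 1.80 ± 0.13 and Krt16 by 4.33 ± 0.35. They were the 3 risen genes among 23 of basal and hyperproliferative keratinocytes, a list with a median of 0.02. A total of 4 rose adjusted over the list alone (camera adjusted p = 0.0185, and adjusted p = 0.331 with an estimated correlation). The risen squamous genes were all of the Sprr2 family, with Sprr2i at 4.50 ± 0.27, Sprr2h at 2.86 ± 0.18 and Sprr2d at 2.71 ± 0.21. These genes share sequence, so the member is uncertain. The filament-associated Hrnr (-1.71 ± 0.19), Ppl (-0.88), Scel (-0.70) and the desmosomal Dsg1a (-0.74) fell. Adjusted over the list alone 4 rose and 14 fell, and the list was lower (camera adjusted p = 0.00127, and adjusted p = 0.465 with an estimated correlation). Of 32 genes of mucous glands and goblet cells the mucus component Fcgbp (1.95 ± 0.22) and Creb3l1 (1.15 ± 0.23) rose, and Agr2 was at 2.24 (adjusted p = 0.0502). In this list 7 rose adjusted over the list alone (camera adjusted p = 0.00129, and adjusted p = 0.220 with an estimated correlation). Without Dox replicate 2 the keratinocyte and mucous lists had adjusted p of 0.0919 and 0.0868, and without NoDox replicate 2 the squamous list had 0.0689. Over the alternatives the adjusted p of these lists ranged from 0.00160 to 0.331, 0.000102 to 0.220 and 4.66e-06 to 0.465. Of 49 cell cycle genes Cenpa (1.05 ± 0.18) and Cdc20 (0.98 ± 0.18) rose, Ccnb2 was at 0.77, and 6 rose adjusted over the list alone (camera adjusted p = 5.14e-05, and adjusted p = 0.213 with an estimated correlation). Of 33 endothelial genes the adhesion genes Selp (1.39 ± 0.17), Icam2 (1.32 ± 0.21) and Icam1 (1.02 ± 0.21) and Plvap (0.77) rose, and 8 rose adjusted over the list alone (camera adjusted p = 7e-05, and adjusted p = 0.213 with an estimated correlation). With 1 array left out the calls of Creb3l1 (0.296) and Icam1 (0.296) were lost in 4 fits, those of Cenpa (0.240), Cdc20 (0.281) and Icam2 (0.162) in 3 and that of Selp in 1, without NoDox replicate 1 (0.0830).

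**Figure D2:**
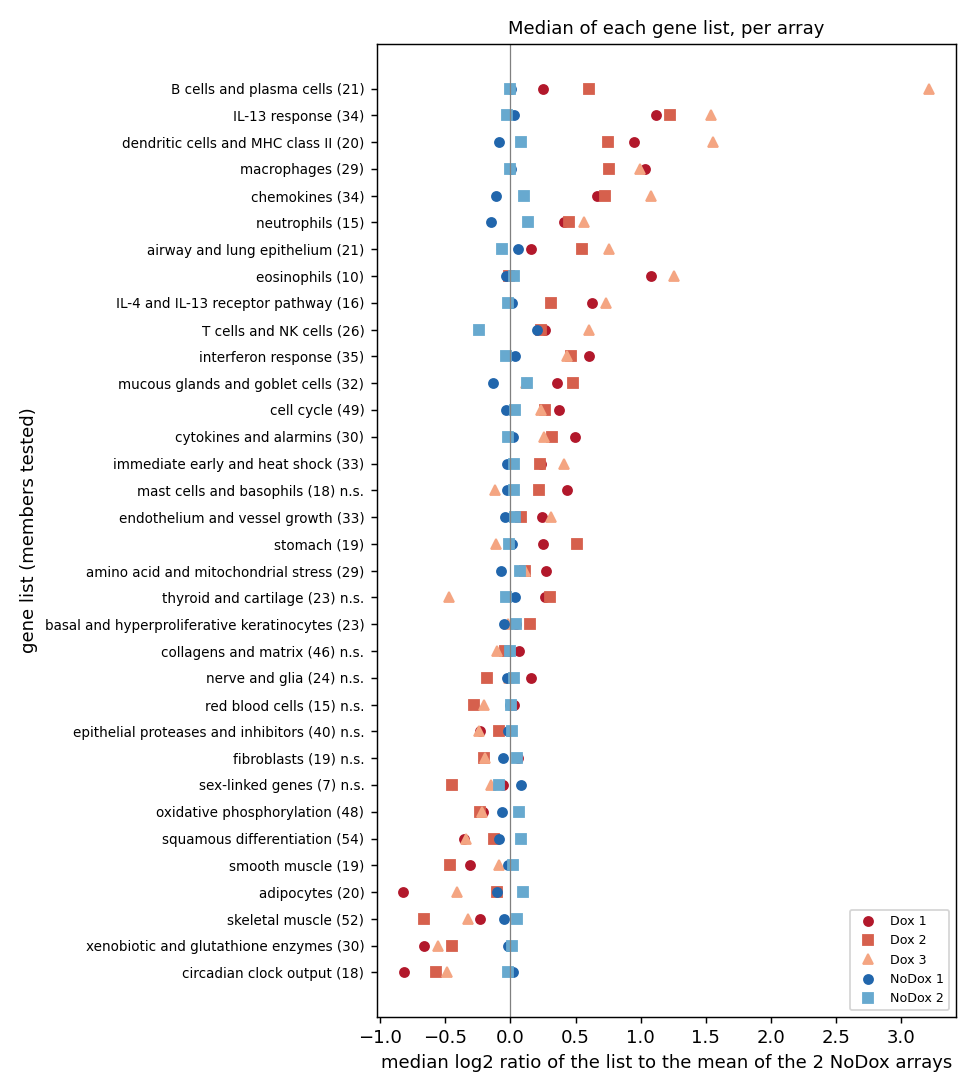
Median log2 ratio to the mean of the 2 NoDox arrays (horizontal axis) of each of the 34 gene lists (vertical axis, members tested in brackets), 1 point per array for 3 Dox and 2 NoDox arrays; n.s. marks lists not past adjusted p under 0.05 in limma's camera test. The Dox medians of the IL-13 response lie at 1.12 to 1.54 and those of the circadian clock list at -0.82 to -0.48.

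Muscle lists shifted downward in Dox at the preset correlation, unevenly between members, and these shifts did not hold with an estimated one. Of 52 skeletal muscle genes 7 fell and 0 rose, 0 had a log2 fold change above 0, and 14 fell adjusted over the list alone (camera adjusted p = 1.87e-13, and adjusted p = 0.269 with an estimated correlation). Myl2, Myh7 and Tnnc1 of slow fibres and Myh4 of fast fibres made the largest falls in the list, and the fast-fibre calcium buffer Pvalb fell by 1.53 on the log2 scale. The abundant muscle genes Acta1 (-0.08), Ckm (-0.15) and Myh1 (-0.11) were not past the threshold. Of 19 smooth muscle genes the integrin Itga8 rose (0.83 ± 0.16), while Cnn1 (-0.79) and Myh11 (-0.71) were not past the threshold. A total of 1 rose and 3 fell adjusted over the list alone, and the list was lower (camera adjusted p = 0.00411, and adjusted p = 0.213 with an estimated correlation). Of 20 adipocyte genes the fatty acid elongase Elovl6 fell (-1.26 ± 0.17), Lep was at -3.91 (adjusted p = 0.0594) and Lpl at -0.61. Adjusted over the list alone 2 fell (camera adjusted p = 0.00128, and adjusted p = 0.354 with an estimated correlation). Itga8 lost its call in 3 fits with 1 array left out (0.277) and Elovl6 in 2 (0.145). Of 48 genes of oxidative phosphorylation 0 passed limma's test over all genes and 0 adjusted over the list alone, and 4 had a log2 fold change above 0. Their median was -0.21, against -0.08 for all genes (camera adjusted p = 2.6e-05, and adjusted p = 0.331 with an estimated correlation). Ndufs1 (-0.58), Uqcrfs1 (-0.46) and Ndufb3 (-0.43) had the smallest p-values. Genes of muscle, a tissue rich in mitochondria, were lower in the same arrays, but a link was not tested.

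Some genes of lung alveoli rose in Dox. Of 21 airway and lung genes the surfactant proteins Sftpc (2.18 ± 0.24), Sftpa1 (2.99 ± 0.37) and Sftpd (2.71 ± 0.35), the surfactant-processing protease Napsa (2.55) and the alveolar type 1 receptor Ager (2.77) rose. Tppp3, a gene of ciliated cells, fell (-0.84). In this list 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.000412, and adjusted p = 0.213 with an estimated correlation). Scgb1a1, the gene of the CC10 promoter, was at 0.79 (adjusted p = 0.147). Of 19 stomach genes Bhlha15 (2.59 ± 0.33), Hdc (3.27 ± 0.48) and Sst (2.94 ± 0.61) rose, and 5 rose adjusted over the list alone (camera adjusted p = 0.00213, and adjusted p = 0.193 with an estimated correlation). Sst was dim, its call ended in all 5 fits with 1 array left out (adjusted p up to 0.243, and 0.0231 to 0.343 over all alternatives), and its log2 fold change shrank to 0.60 with the larger offset. Hdc (0.110), Sftpc (0.0618), Sftpa1 (0.0800) and Sftpd (0.105) lost their call in 2 fits, Hdc shrank to 1.46 with the larger offset, and Bhlha15 to 1.06 with the mean of its probe sets. Bhlha15 is also a gene of plasma cells, and Hdc, which forms histamine, of mast cells and other leukocytes.

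Lists of the circadian clock and of xenobiotic metabolism shifted downward at the preset correlation and 2 lists of stress genes upward, and none of these shifts held with an estimated one. With fry the clock list passed the threshold (fry adjusted p = 0.0377) and the others did not. Of 18 clock genes Nfil3 (2.22 ± 0.23) and Arntl (adjusted p = 0.0203) rose, while Per3 (-1.29 ± 0.14), Dbp (2.82-fold lower), Tef (-0.78), Per1 (-1.04), Nr1d2 (-0.80) and Wee1 (-1.04) fell. A total of 3 rose and 11 fell adjusted over the list alone (camera adjusted p = 0.000283, and adjusted p = 0.165 with an estimated correlation). Of 30 genes of xenobiotic and glutathione enzymes 7 fell, among them the alcohol dehydrogenases Adh7 (-1.32 ± 0.19) and Adh1 (-0.91 ± 0.15) and Cyp3a13 (-0.85 ± 0.13), and Cyp2b10 rose (0.72). Adjusted over the list alone 2 rose and 19 fell (camera adjusted p = 8.14e-07, and adjusted p = 0.213 with an estimated correlation). Of 33 immediate early and heat shock genes 0 passed limma's test over all genes, with Klf2 at 0.60, Hspa1a at 0.73 and Egr1 at 0.90. In this list 9 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.26e-05, and adjusted p = 0.213 with an estimated correlation). Of 29 genes of amino acid and mitochondrial stress Nupr1 rose (1.21 ± 0.15), and Asns (0.62) and Ddit4 (-0.79) were not past the threshold. A total of 5 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00213, and adjusted p = 0.331 with an estimated correlation). With 1 array left out the calls of Adh1 (0.231) and Cyp3a13 (0.175) were lost in 3 fits and those of Per3 (0.0830), Dbp (0.0700), Adh7 (0.143) and Nupr1 (0.105) in 2. Without NoDox replicate 1 the list of amino acid and mitochondrial stress had adjusted p = 0.0630, in a range over the alternatives of 0.000344 to 0.331.

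The remaining lists were not past the threshold in limma's camera test, at either correlation. Among 46 collagen and matrix genes Fn1 (0.96), Mmp14 (0.79) and Timp1 (1.36) rose and Col8a1 fell (-1.20), with 4 higher and 1 lower adjusted over the list alone (median -0.03, camera adjusted p = 0.213, and adjusted p = 0.588 with an estimated correlation). Among 40 epithelial proteases and inhibitors Stfa3 (1.67) and Klk6 (2.82-fold) rose and Serpinb7 (-1.54), Spink5 (-1.10) and Serpinb8 (-0.98) fell, with 7 higher and 12 lower adjusted over the list alone (median -0.14, camera adjusted p = 0.248, and adjusted p = 0.514 with an estimated correlation). Of 18 mast cell and basophil genes Hdc rose, also adjusted over the list alone (median 0.25, camera adjusted p = 0.194, and adjusted p = 0.429 with an estimated correlation). Fibroblast, nerve and glia, thyroid and cartilage, red blood cell and sex-linked genes had 0 members past limma's threshold, both over all genes and adjusted over the list alone. Their medians were -0.16, -0.03, 0.08, -0.13 and -0.18. Their camera adjusted p were 0.207, 0.632, 0.297, 0.945 and 0.630, and adjusted p = 0.656, 0.813, 0.741, 0.946 and 0.768 with an estimated correlation. The collagen, nerve and red blood cell lists had means above 0 (0.06, 0.02 and 0.19) and medians below it. Xist was at -0.13, Eif2s3y at -0.29, Kdm5d at -0.18 and Uty at -0.41, none past the threshold. Ddx3y was not analysed here. Relative to the NoDox arrays, the 3' over 5' ratio of the Gapdh control was 0.993, 1.02 and 1.08 in the Dox arrays, and that of beta-actin 1.08, 1.10 and 1.18.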

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

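The tests of the muscle share, of fibre-type genes against the diet and of the NoDox signal of heart and alveolar genes were chosen after the result was seen, and the others in this part before.

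Among the 10092 probe sets with several or no gene symbols, which no comparison above uses, limma called 30 higher and 11 lower in Dox. They stood out as changes in data outside the gene-level test. Bacterial control probe sets, also outside it, reached a ratio of 23.1 in Dox replicate 2. The same probe set was at 1.16 and 6.40 in Dox replicates 1 and 3. It stood out as the highest ratio of a control. NoDox ratios cannot exceed 2 by construction, so they give no reference for it. The hybridization controls stayed between 0.875 and 1.36 in the Dox arrays.

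Of 13 slow-fibre muscle genes 4 fell in Dox, Myl2, Myh7, Tnnc1 and Myoz2, and of 14 fast-fibre genes 2, Myh4 and Pvalb, with medians of -1.18 and -0.32. A smaller share of muscle as a whole would lower both fibre types alike. The fast-fibre median, -0.32 (95% bootstrap interval -0.53 to -0.16), lay above all 4 of these slow-fibre falls, the smallest of them Myoz2 (-1.22). Those 4 genes were picked for their falls, and the fast-fibre Myh4 (-3.06) and Pvalb (-1.53) fell more than Myoz2. The comparison of fibre types therefore decides nothing. Yet Myl2 (-5.96 ± 0.35), Myh7 (-4.04 ± 0.25) and Tnnc1 (-2.96 ± 0.22) fell far more than muscle genes in general. The median of the 52 skeletal muscle genes was -0.43. Among genes not past the threshold the fast-fibre median lay 0.0563 above the slow-fibre one, and the slow-fibre interval (-1.53 to 0.154) held 0. A smaller share of all muscle would not lower Myl2, Myh7 and Tnnc1 so far beyond the medians of -0.32 and -0.43. The values argue against it as the whole cause of these falls, and it stays open for the smaller changes. Heart tissue in the NoDox samples would bring genes of heart muscle that skeletal muscle lacks. The median of 14 such genes was 0.33 (95% bootstrap interval -0.26 to 0.77). Only 4 of them lay above the median signal level, and these 4 fell, from -0.94 (Myl7) to -0.14, none as far as Myoz2. In NoDox 5 contractile ones, Myh6, Tnni3, Tnnt2, Mybpc3 and Myl7, reached at most 27362 steps, against 49511 or more for Myl2. Myl4, whose level was not recovered (lower bound 15.3 in log2 steps), was left out of this maximum. Signals of different probe sets also need not share a scale. Most of these genes were dim also in NoDox, where heart tissue would raise them. The 4 brighter ones fell far less than Myl2, Myh7 and Tnnc1, and the median of the 14 did not fall. These values argue against heart tissue as the main source of the falls of Myl2, Myh7 and Tnnc1. A smaller amount of heart tissue stays open, since the brighter genes fell. A change of fibre-type genes with the diet may apply, and the median difference of 0.86 between all fast-fibre and slow-fibre genes rests on the genes that raised the question and decides nothing.

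Of 5 clock genes in phase with Arntl 2 rose in Dox, and of 10 in phase with Dbp 5 fell. The median log2 fold change of the former (95% bootstrap interval -0.15 to 2.22, with Clock at -0.15 and Cry1 at -0.11) lay 1.96 above that of the latter (permutation p = 0.00515 over genes). The permutation treats genes read on the same 5 arrays as independent, so its p does not measure the spread between samples. The gap also rests in part on the genes that raised the question. A different time of day at collection would part the phases this way, and may be the cause. A change of the clock with the diet would also move clock genes, of which 8 passed the threshold, and cannot be told apart from the time of day, since the labels give no time of collection.

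In Dox 5 alveolar lung genes rose, Sftpc, Sftpa1, Sftpd, Napsa and Ager, while of 18 others 2 passed the threshold. The lowest NoDox signal of Sftpa1 and Sftpd was 9035 steps, above the median of all probe sets (3652), which argues against noise of dim probe sets for these 2. The signal of Sftpc was not recovered. The lower bound of its mean level over the 5 arrays, 15.6 in log2 steps, lay above the level of Sftpd (15.0). Sftpc also rose less than Sftpd (2.18 against 2.71), which argues against such noise for Sftpc too. The lowest NoDox signal of Napsa and Ager was 3116, below the median, so noise stays open for these 2. A level filter with an offset kept all 445 changed genes it tested and decides nothing. Lung tissue in the Dox samples would raise other alveolar genes too, and the median of the others was 0.40 (95% bootstrap interval -0.06 to 0.80), with Car4 (2.46) and Slc34a2 (1.91) past the threshold. Lung tissue and a rise of surfactant genes in the esophagus itself cannot be told apart at this value, and either may apply.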

How the results depend on the processing

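The level filter at the median, the offset of the 20th percentile, both together, the first recovery rule and the mean log2 ratio in place of the recovered level, in both its uses or in 1 of them, were chosen after seeing the data; the others were planned. The planned settings with no filter and no offset equal the fit as reported. Where a cause is not given, the cause was not tested.

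With the mean log2 ratio for both the trend and the probe set, the plan read to the letter, the counts of 249 higher and 213 lower genes became 0 and 0 (2180 genes at unadjusted p under 0.05 in limma). For the trend alone they were 0 and 0 (2363), for the probe set alone 259 and 119, and with no intensity trend 6 and 0 (2421). The larger offset gave 159 and 117, array weights 452 and 501, and adjusted p under 0.1 458 and 490. Each offset was added only to probe sets with a recovered level. Lower genes numbered 125 with quantile normalization, 331 with filter and offset and 96 with a 2-fold limit, and higher genes 588 at unadjusted p under 0.05 with a 2-fold limit. With the replicate number as a block there were 359 higher and 460 lower, but nothing in the labels ties arrays by number beyond the pair-wise normalization they name, and the deviations of same-numbered arrays correlated at 0.0311 and 0.0519.

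Leaving out 1 array in turn gave 59 to 377 higher and 8 to 486 lower genes. The counts were 377 and 486 without Dox replicate 2, 117 and 47 without Dox replicate 3, 59 and 8 without NoDox replicate 1 and 64 and 11 without NoDox replicate 2. A lone NoDox array is assumed to vary like the Dox arrays. Of 69 named genes past the threshold 28 kept their call in all these fits, and of 26 lists 19 did.

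Of the 19 higher and 7 lower lists, 1 and 0 passed with an estimated correlation, 6 and 1 with fry, and 12 and 4 with the filter at the 75th percentile, which left 5 of these lists untested (eosinophils, neutrophils, T and NK cells, mucous glands and stomach). With fry the 6 were the IL-13 response, the IL-4 and IL-13 receptor pathway, chemokines, eosinophils, macrophages and the interferon response. The lower one was the circadian clock.

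Among the 69 named genes past the threshold 1 changed sign, Per3, to 0.0404 with the mean log2 ratio, which picks another probe set, as it does for the other genes and the list below that change sign with it. They change alike with the mean log2 ratio for the probe set alone. Of all genes past the threshold 438 of 462 kept their sign with the mean log2 ratio, 459 of 462 with the mean of probe sets and 446 of 451 without shared probe sets. Among named genes not past it, Stat6 went to 0.0957 with quantile normalization and 0.0362 with median centring, Uty to 0.0240 with the mean of probe sets and 0.53 with the mean log2 ratio, and Kdm5d to 0.18 with the latter. Xist went to 0.96 without shared probe sets, 0.96 with the mean log2 ratio and 0.0426 without Dox replicate 2 (from -0.30 with 1 array left out), and Iglv1 to -2.86 without shared probe sets.

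Lists whose tested direction reversed were not past the threshold in either fit. The red blood cell list reversed with means of 0.20 (quantile), 0.27 (centring), -0.0557 (larger offset), -0.14 (median filter), -0.0147 (offset), -0.15 (both), 0.19 (fry), 0.0355 without Dox replicate 1 and 0.23 without NoDox replicate 1 (up to 0.27 with 1 array left out). The nerve and glia list did at -0.12 (filter at the 75th percentile) and -0.0160 (replicate block), and the sex-linked list at 0.29 (mean log2 ratio) and 0.00468 without NoDox replicate 1 (from -0.20 with 1 array left out). Signal level limits the test, since dim genes were 37.5% of those tested and 7.79% of those past the threshold.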

Other observations

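In a further list of 20 genes shared by leukocytes, 19 were above 0 in Dox, with a median log2 fold change of 1.17. Of these 4 passed limma's threshold, Itgb2 (1.98), Laptm5 (1.57), Cd53 (1.44) and Rac2 (1.33). Every gene of the list had its highest ratio in Dox replicate 3. In Dox replicates 1, 2 and 3 the ratios of Laptm5 were 2.46, 2.38 and 4.46, while those of Itgb2 were closer together (4.06, 3.61 and 4.16).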
